A study of Drosophila melanogaster with 4 samples.

How the data were processed

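Chromatin from heads of wild-type Oregon-R Drosophila melanogaster adults was cross-linked with formaldehyde, sonicated and immunoprecipitated with the antibody NRO3 against ubiquitylated histone H2B (H2Bub), per the labels' protocols. The series holds 2 ChIP samples and 2 input samples, numbered replicate 1 and replicate 2 in each kind. The labels pair each ChIP replicate with the input of the same number. Nothing in the labels says whether the replicates came from separate fly populations, so agreement between them may measure technical spread only.

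The values used here are 3 lists of genomic regions, called clusters in the deposited files: 1 list per ChIP replicate and 1 combined list for the series. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers, and chromosome lengths were taken from the same headers. The authors gave each deposited cluster a start, an end and a score. The scale of that score, the cluster caller, its threshold, any minimum width and the way in which the combined list was made are not given in the sources used here. The score is the authors' own value per cluster and was used to rank, describe or split clusters within a list. It was also correlated between paired clusters of the 2 replicate lists. Differences in score between X and autosomal clusters were taken within each list and then averaged over the replicates. Every region of the replicate lists is typed as significant enrichment. The combined list also holds 2 regions typed as significant depletion, which were kept out of all counts of clusters. No read counts were used, so sequencing depth is unknown and no error of the score could be computed. The inputs enter only through whatever use the authors made of them; no input profile was analysed here.

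Coordinates were treated as 1-based and inclusive. A cluster counted as shared when it overlapped a cluster of the other list by at least 1 bp. Shared bases were expressed as the Jaccard index, the shared length over the length covered by either list. Chance overlap was taken from 1000 circular shifts of the replicate 2 clusters within each chromosome, with a one-sided permutation p whose smallest possible value is 0.000999. The same number of shifts of each list gave chance shares by cluster width, also for the midpoint of a cluster, a criterion that wide clusters do not meet more easily by chance. Shares of clusters carry 95% Wilson intervals, which cover counting error only and treat clusters as independent. Scores were correlated over clusters that pair 1 to 1 between replicates, with 100000 permutations. Covered share is the summed cluster length over the length of the chromosome, given as mean ± SD over the 2 replicates. The arms X, 2L, 2R, 3L and 3R were also cut into 117 full windows of 1000000 bp, and X windows were compared with autosomal windows by a two-sided permutation test with 100000 resamples, in covered share and in number of cluster midpoints. Windows that reach into the 2 Mb at the centromere end of an arm are called proximal. Neighbouring windows and clusters are not independent replicates, so these p-values describe the libraries at hand. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and bedtools 2.31.1.

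The overlap code was tested on simulated data. Against a copy of the replicate 1 list that kept 90.1% of its 5440 clusters, it recovered a shared share of 90.1%. Among 100 runs on the replicate 1 list against a randomly shifted version of itself, 2 gave a shift p under 0.05.

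Tests, alternatives, lists and the rule for named regions were fixed before the data were examined. The rule names the 10 clusters with the highest score in the combined list and its 5 widest, by position. Further regions, the 3 highest and 3 lowest windows and the 5 longest stretches without a cluster, were chosen after the data were seen. So were the tests of score rank and width between clusters, of the density, width and scores of X clusters against autosomal ones, with the alternatives run on the X score difference, of proximal windows and of the stretches without clusters. The window comparison was added to the planned tests before its result was seen. Planned comparisons with genes (position relative to genes, genes covered, gene length, and 20 gene lists) were not run, because the gene table at hand is for release 6 of the genome and its coordinates cannot be set against release 5. Clusters are therefore reported by position without gene names. Alternatives were a stricter score threshold (the upper 50% of each list), merging of clusters less than 1000 bp apart, restriction to the chromosome arms, a reciprocal overlap of 50%, random placement in place of circular shifts, and leaving out each replicate in turn.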

Results

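H2Bub, a histone modification known from gene bodies of transcribed genes, was mapped by ChIP-seq in nuclei from heads of wild-type Oregon-R adults. The series holds 2 ChIP replicates, each with its own input, of a single antibody, strain and tissue. The comparisons it allows are therefore between the replicates, between each replicate and the authors' combined list, and between parts of the genome. The replicate 1 list held 5440 enriched clusters and the replicate 2 list 5597, a mean of 5518.5 ± 111 (SD, n = 2). Sequencing depth is unknown, since the lists give regions and scores but no read counts.

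H2Bub clusters covered 27.7 to 28.6% of the assembled chromosome arms and ranged from short regions to domains of about 100 kb. They covered 33.5 Mb in replicate 1 and 34.6 Mb in replicate 2 (arms X, 2L, 2R, 3L, 3R and 4, and scaffolds). The median cluster was 3389 bp wide in replicate 1 and 3427 bp in replicate 2, and the narrowest was 1301 bp in both. The widest cluster, on 3L, measured 105892 bp in replicate 1 and 106243 bp in replicate 2. Domains over 10 kb made up 14.9% and 15.3% of clusters but held 50.1% and 50.4% of the covered bases. Wider clusters carried higher scores, with a Spearman's rho across clusters of 0.80 in replicate 1 and 0.81 in replicate 2; clusters within a library are not independent replicates.

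Both replicates marked largely the same regions. Of the replicate 1 clusters, 5058 of 5440 overlapped a replicate 2 cluster (93.0%, 95% Wilson interval 92.3 to 93.6%), and 4930 of 5597 replicate 2 clusters overlapped a replicate 1 cluster (88.1%, 87.2 to 88.9%). Circular shifts of a list within chromosomes gave mean shares of 42.0% for replicate 1 and 41.0% for replicate 2, with maxima of 49.2% and 47.9% over 1000 shifts. Wide domains were shared without exception: all 809 clusters over 10 kb of replicate 1 and all 856 of replicate 2 had a partner in the other list, against 60.5% and 59.4% on average under the shifts. Narrow clusters were shared less often. Among clusters of up to 2 kb, 75.5% of those in replicate 1 (73.1 to 77.9%) and 60.0% of those in replicate 2 (57.3 to 62.6%) had a partner, against 98.1% and 96.5% of wider clusters (two-sided Fisher's exact p = 6.8e-133 and 6.2e-229). A narrow cluster also meets the other list less often by chance, with shift means of 34.1% and 32.9% against 44.4% and 43.5% for wider clusters. By the midpoint alone, for which the shifts gave 28.2% and 27.2% of narrow and 28.4% and 27.5% of wider clusters, 67.9% and 53.2% of narrow clusters lay inside a cluster of the other list, against 96.2% and 93.6% of wider ones (two-sided Fisher's exact p = 2.6e-150 and 4e-227). The midpoint evens out chance overlap only. Where the replicates differ in the bounds of a cluster, the midpoint of a narrow one falls outside more easily, so this effect of width remains. When at least 50% of both clusters had to overlap, 77.3% and 75.1% of clusters were shared. Some domains called whole in one replicate were called in pieces in the other, and 445 clusters of replicate 1 and 560 of replicate 2 spanned 2 or more clusters of the other list.

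In bases, the lists shared 31.4 Mb, with a Jaccard index of 0.855. Circular shifts of replicate 2 within chromosomes gave a mean of 0.164 and a maximum of 0.242 over 1000 shifts (one-sided permutation p = 0.000999, the smallest the shifts can give). Among 3645 clusters that paired 1 to 1, scores correlated with a Spearman's rho of 0.93 and a Pearson's r of 0.95 (permutation p = 1e-05 for each, the smallest possible). Start positions of a pair differed by a median of 135 bp and ends by 138 bp, and no pair had identical bounds. The 382 clusters called only in replicate 1 had a median width of 1583 bp and a median score percentile of 21.9 within their list, against 3675 bp and the 52.8th percentile for shared clusters. For the 667 clusters called only in replicate 2 the values were 1620 bp and 18.7, against 3905 bp and 55.6. The statistic tested was the difference in mean score percentile, which in both replicates exceeded all 100000 permutations of the clusters (two-sided permutation p = 1e-05). These single-replicate clusters held 2.03% and 3.45% of the covered bases.

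The authors' combined list was longer than either replicate list: it added narrow clusters found in neither replicate and also held more clusters over 10 kb. It held 6056 enriched clusters over 40.3 Mb, or 33.3% of the arms. Its median cluster was 3485 bp wide, and 1023 clusters (16.9%) exceeded 10 kb, against 809 and 856 in replicates 1 and 2. Of these, 4093 (67.6%, 66.4 to 68.8%) overlapped clusters of both replicates and carried 91.1% of the combined bases. Another 296 overlapped replicate 1 only and 542 replicate 2 only. The remaining 1125 clusters (18.6%, 17.6 to 19.6%) overlapped neither list, had a median width of 1315 bp and made up 4.11% of the combined bases. Of the 3.72 Mb of combined bases outside both replicate lists, 2.06 Mb lay in clusters that overlapped a replicate cluster and 1.66 Mb in these 1125. Nearly all replicate clusters were kept: 5430 of replicate 1 and 5587 of replicate 2 overlapped a combined cluster. Every one of the 383 combined clusters of 20 kb and over was present in both replicates.

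**Figure D1:**
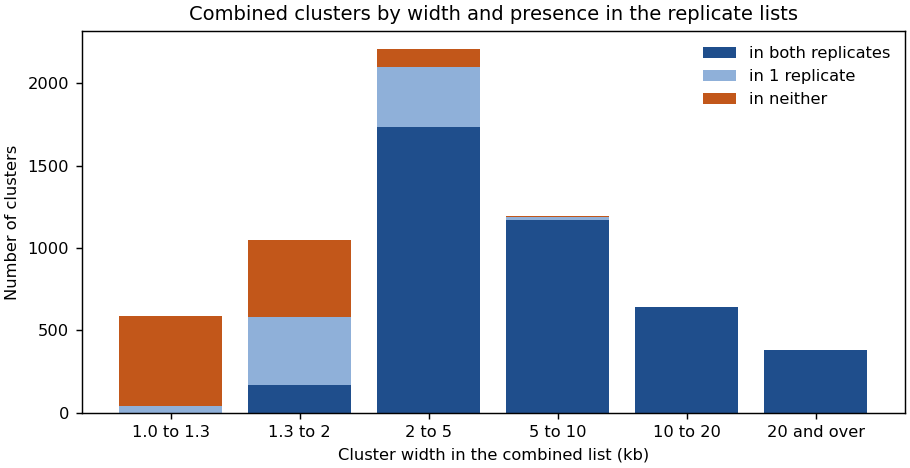
Number of clusters in the combined list (vertical axis) by cluster width in kb (horizontal axis); colours show whether a cluster overlapped both replicate lists, 1 of them or neither by at least 1 bp. Clusters found in neither list were narrow: 545 of the 1125 were below 1301 bp, and none was 10 kb or wider.

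Along the genome, clusters took similar shares of X and the large autosomal arms, a lower share of the small chromosome 4 and were sparse on heterochromatic scaffolds. Covered share was 27.4 ± 1.55% on X, 27.8 ± 0.280% on 2L, 29.5 ± 0.636% on 2R, 26.8 ± 0.326% on 3L and 30.0 ± 0.410% on 3R (mean ± SD, n = 2). On chromosome 4, known for its interspersed heterochromatin, it was 12.6 ± 2.24%, which is 0.439 ± 0.0721 of the share of the large autosomal arms together. This ratio fell to 0.247 when only the upper 50% of clusters by score was used. The heterochromatic scaffolds XHet, 2LHet, 2RHet, 3LHet, 3RHet and YHet together reached 1.28 ± 0.169%. YHet, from the Y chromosome, held no cluster in either replicate and 1 in the combined list. On the unplaced scaffold U the share was 0.154 ± 0.0123%, and Uextra held no cluster in any list. No test was made across 2 replicates of 1 condition. Shares are of the full sequence length, and the part that reads can be mapped to was not measured. Low shares on chromosome 4, on scaffolds and in proximal windows could therefore also come from sequence that reads cannot be mapped to.

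**Figure D2:**
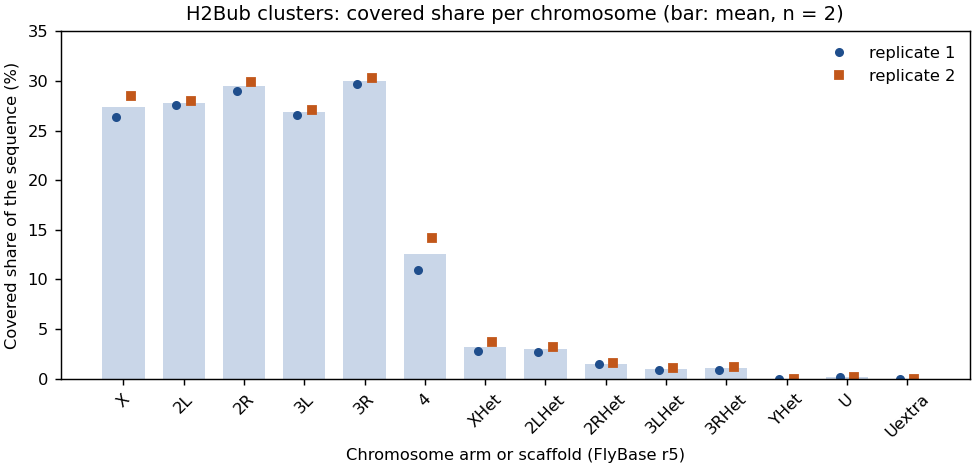
Share of each chromosome arm or scaffold covered by H2Bub clusters, in percent (vertical axis); circles and squares are replicates 1 and 2 and bars their mean. X and the 4 large autosomal arms had means between 26.8 and 30.0%, chromosome 4 had 12.6%, and no scaffold mean exceeded 3.24%.

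The X differed from the large autosomal arms in how its coverage was made up. Covered share over windows of 1 Mb was 26.6% on X (22 windows) and 28.4% on the autosomal arms (95 windows) in replicate 1, and 28.8% and 29.0% in replicate 2. Neither difference exceeded the variation between windows (two-sided permutation p = 0.346 and 0.925). X clusters were more numerous, at 52.5 ± 0.0315 per Mb against 43.8 ± 1.03. Taken one by one, the autosomal arms had means from 41.1 on 2L and 3L to 48.1 on 2R. Over the same windows X exceeded the autosomal arms together by 9.44 clusters in replicate 1, 7.83 in replicate 2 and 8.60 in the combined list (two-sided permutation p = 0.00182, 0.00905 and 0.00417). X clusters had a lower mean width, 5221 ± 292 bp against 6521 ± 60.7 bp, with a ratio of 0.764 in replicate 1, 0.838 in replicate 2 and 0.876 in the combined list (two-sided permutation of clusters, p = 1e-05, 0.00012 and 0.00339). Median width was also lower on X in the replicates, at 3029 against 3619 bp in replicate 1 and 3206.5 against 3554 bp in replicate 2 (p = 2e-05 and 0.00575 by the same permutation). In the combined list the medians of 3501 and 3579 bp did not pass the permutation test (p = 0.589), and 2R had a lower median than X, 3327 bp. Adjusted over these 9 tests, p was at most 0.0102 except for the combined median. Merging of nearby clusters was not applied to these comparisons, so a difference in how domains were split was not tested. Clusters on X also ranked higher by score: their median percentile within the list was 58.5 ± 0.908, against 45.5 to 46.8 on the 4 autosomal arms taken one by one. The difference in median percentile from the autosomal arms together was 13.4 points in replicate 1, 11.0 in replicate 2 and 6.98 in the combined list. Mean percentile differed by 10.6 points in replicate 1 and 10.2 in replicate 2. Within each replicate, 100000 permutations of the clusters between X and autosomes gave a two-sided permutation p = 1e-05, the smallest possible. The higher rank of X clusters did not extend to the strongest ones. Among the 100 highest scores, 8 in replicate 1 and 10 in replicate 2 lay on X, although X held 21.6% and 21.0% of clusters (two-sided Fisher's exact p = 0.000228 and 0.00308 against the autosomal arms). This count was not matched for width, and score rose with width. With only the upper 50% of clusters by score, the difference in median percentile turned from 12.2 to -9.50 points. That setting selects on the score it compares, so it restates the narrower spread of X scores and is no separate check.

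**Figure D3:**
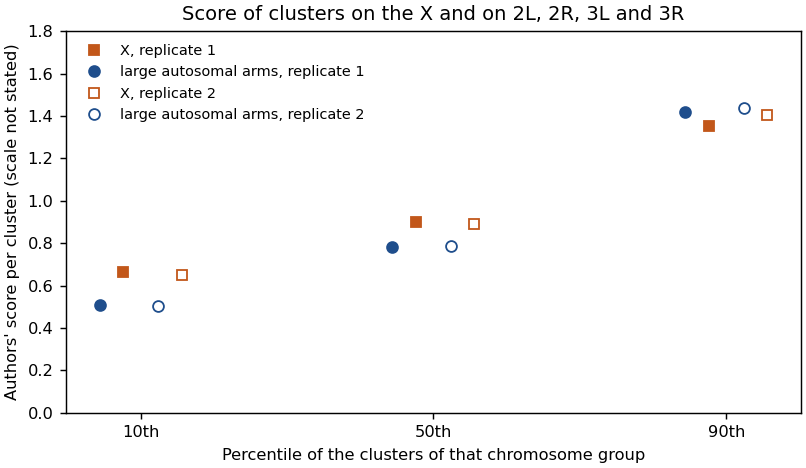
Authors' score per cluster (vertical axis, scale not stated) at the 10th, 50th and 90th percentile of clusters on X (squares) and on the large autosomal arms (circles), for replicate 1 (filled) and replicate 2 (open). At the 10th percentile X clusters lay above autosomal ones (0.663 against 0.506 in replicate 1), and at the 90th percentile below (1.35 against 1.42).

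At the scale of 1 Mb the replicates followed the same profile. Over 117 windows on the 5 large arms, covered share ranged from 5.32% to 54.2% with a median of 28.6%, and the replicates differed by at most 6.01 percentage points. Across windows, Pearson's r was 0.99 and Spearman's rho 0.98. The highest share, 54.2 ± 0.224%, was on 3R from 5000001 to 6000000, followed by 45.2 ± 1.72% on 2R from 6000001 to 7000000 and 44.0 ± 0.921% on 3R from 1000001 to 2000000. The 3 lowest windows were all proximal: 3L from 23000001 to 24000000 (5.32 ± 0.360%), 2L from 22000001 to 23000000 (5.45 ± 0.0837%) and 2R from 1 to 1000000 (6.58 ± 0.925%). In replicate 1, proximal windows averaged 13.4% on 2L against 29.0% elsewhere on that arm, 13.3% against 30.9% on 2R, 15.0% against 27.8% on X and 20.0% against 27.8% on 3L. Arm 3R went the other way, with 33.2% in its proximal windows and 29.2% elsewhere. Replicate 2 gave the same order on each arm, with 34.6% against 29.7% on 3R. Averaged over the 5 arms, proximal minus other windows came to -9.94 percentage points in replicate 1 and -9.92 in replicate 2 (permutation of windows within arms, two-sided p = 0.00018 and 0.00024). Arm by arm, with 2 proximal windows each, X, 2L and 2R passed an exact two-sided permutation test in both replicates (p = 0.00433, 0.0158 and 0.00476, adjusted to 0.0119, 0.0264 and 0.0119 over the 5 arms), whereas 3L (p = 0.181 and 0.188, adjusted to 0.226 and 0.236) and 3R (p = 0.556 and 0.467, the same after adjustment) did not. Only full windows counted, which left out the centromere ends of X, 2L and 3L beyond the last one. On 3L that end held a stretch of 324665 bp without a combined cluster. The 3L window from 22000001 to 23000000, with 35.2% covered, lay only partly within the proximal 2 Mb. The 3L result may therefore depend on where the windows fall.

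**Figure D4:**
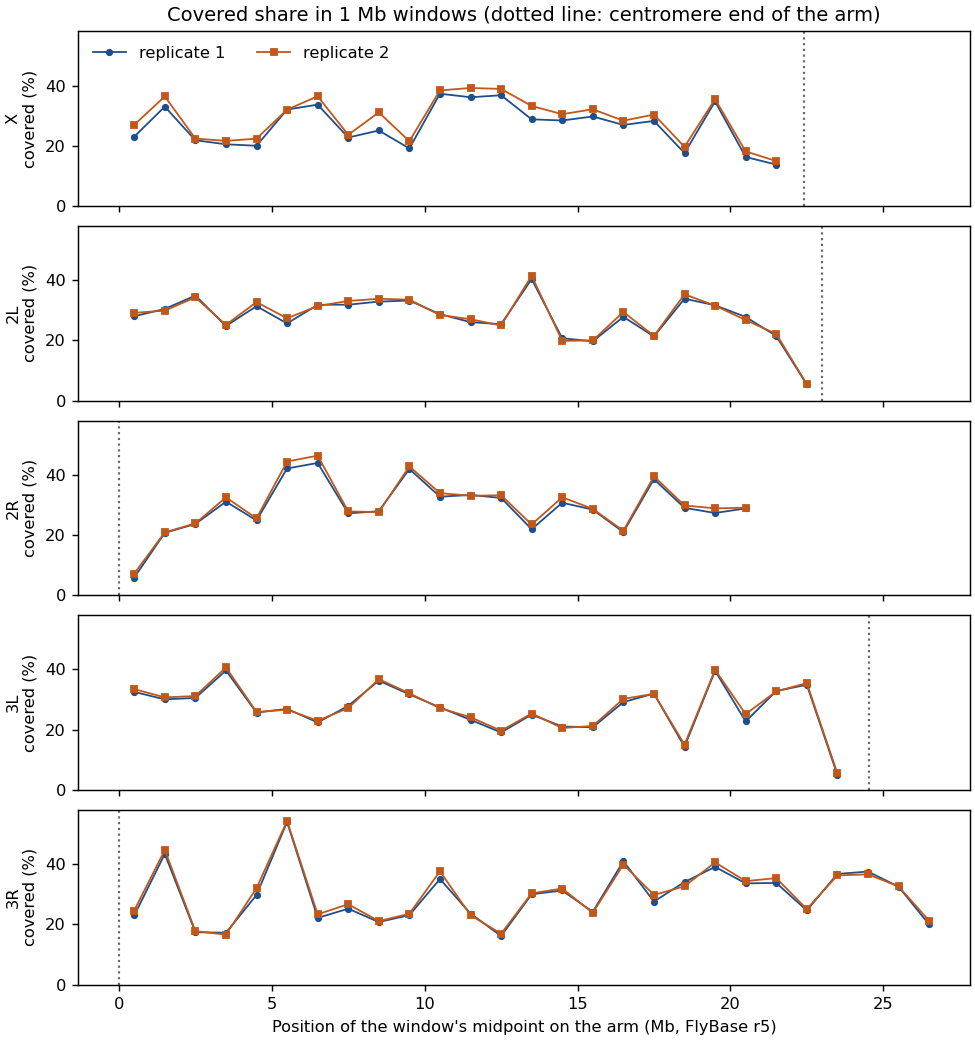
Share of each 1 Mb window covered by H2Bub clusters, in percent (vertical axis), against the window's position in Mb on X, 2L, 2R, 3L and 3R (horizontal axis); circles are replicate 1, squares replicate 2, and the dotted line marks the centromere end. Both replicates traced the same peaks and troughs, with the maximum of 54.2% on 3R and low windows near the centromere ends of 2L, 2R and 3L.

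Clusters were bunched rather than evenly spaced. The median stretch between neighbouring combined clusters on the 5 large arms was 2747 bp, yet 139 stretches exceeded 100 kb and together made up 19.0% of those arms. Random placement of the same clusters without overlap gave a mean of 4.26 and at most 12 such stretches in 1000 draws (one-sided permutation p = 0.000999). Pieces of a split domain lie side by side, whereas the draws placed them apart, so splitting may add to this contrast. Merged clusters were not tested in this way. Longest of all was 3L from 18177557 to 18634945, 457389 bp, followed by 3R from 2485695 to 2890491 (404797 bp) and X from 9579165 to 9953821 (374657 bp). None of these 3 held a cluster in either replicate. The next were 3L from 23334389 to 23707581 (373193 bp), which held 1 cluster of replicate 2, and 2L from 21759803 to 22121271 (361469 bp), which held none. Such a stretch shows only that the combined list held no enriched cluster there, which sequence that reads cannot be mapped to would also give.

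The clusters with the highest scores in the combined list fell into 2 kinds. The top 4 were about 1 kb wide and were present in neither replicate: 3LHet from 1257282 to 1258282, 3L from 24096314 to 24097388, U from 7856974 to 7858016 and X from 9402252 to 9403252, with scores from 2.51 to 2.30. Ranks 5 to 10 were wider and present in both replicates, where they also ranked among the first 11. They lay on 3R from 22950490 to 22967324 (16835 bp), 3L from 1575948 to 1602882 (26935 bp), 3R from 27230424 to 27239834 (9411 bp), 3L from 748612 to 756254 (7643 bp), 2L from 161614 to 202390 (40777 bp) and 2R from 4501416 to 4511866 (10451 bp). The 3L domain of 26935 bp held the highest-scoring cluster of each replicate list.

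The 5 widest combined domains were each more than 92% covered in either replicate. The widest spanned 106499 bp on 3L from 22294998 to 22401496 and was called as 1 cluster in each replicate. Another 3 wide domains lay on 2R, from 15422132 to 15519212 (97081 bp), from 17281122 to 17374650 (93529 bp) and from 9509968 to 9601694 (91727 bp). The other one, on 3L from 19136572 to 19228642 (92071 bp), was broken into 8 clusters in replicate 1 and 6 in replicate 2. These domains ranked 109, 539, 65, 1338 and 830 by score, in order of width.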

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

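No paired analysis was possible because the inputs have no cluster list among the files used here and no result comes from a test between groups. With 2 replicates, leaving out each in turn restates the values of the other and is no separate check. It gave 5440 to 5597 clusters, 33.5 to 34.6 Mb covered, 26.3 to 28.5% of X and 11.0 to 14.1% of chromosome 4. The X difference in score percentile was 11.0 to 13.4 points. The X score difference and its alternatives, and the midpoint criterion, were chosen after seeing the data. The Jaccard index stayed beyond chance with the upper 50% by score (0.840), with merging (0.861) and against random placement (highest random value 0.175), and rho was 0.93 under reciprocal overlap. Keeping the upper 50% of each list by score gave 2759.5 clusters by construction, and with them 26.8 Mb and a median width of 6303 bp. It gave covered shares of 23.4% on X, 21.5% on 2L, 22.7% on 2R, 20.8% on 3L, 23.5% on 3R and 5.51% on 4, an X to autosome ratio of 1.06 in place of 0.960 and a chromosome 4 ratio of 0.247. The same setting reversed the X difference in score percentile to -9.50 points, but it selects on the score being compared, so this is no independent check. It also reversed the window difference between X and autosomes to 0.90 points in replicate 1 (permutation p = 0.589) and 1.98 in replicate 2 (p = 0.240). The cause was not tested. Without the windows next to the centromeres, an alternative chosen after seeing the data, the difference was -1.39 points in replicate 1 (permutation p = 0.414) and 0.29 points in replicate 2 (p = 0.865). Shared clusters came to 91.2% and 87.0% with the upper 50% and 77.3% and 75.1% with reciprocal overlap of 50%, and merging gave 89.3% for replicate 2 and a median width of 4645 bp. Combined clusters found in both replicates were 57.3% with reciprocal overlap, 74.5% with the upper 50% and, chosen after seeing the data, 74.8% among clusters of at least 1301 bp. By midpoint, the shared share of narrow minus wider clusters was -28.3 and -40.4 points, in place of -22.6 and -36.5 by 1 bp. Of the 15 named clusters, the domains of 92071 and 91727 bp were held by 0 and 1 replicate lists under reciprocal overlap, in place of 2 each. Without read counts, the part that depth plays in the narrow, low-scoring clusters called in only 1 list cannot be measured.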

Other observations

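The 2 regions that the combined list types as significant depletion were enriched clusters in a single replicate. One, on 2L from 12044956 to 12046612 with a score of -0.0094, lay wholly under a replicate 2 cluster and under none of replicate 1. The other, on 2R from 8510734 to 8512488 with a score of -0.017, was 98.9% covered by a replicate 1 cluster and by none of replicate 2. Those replicate clusters were the second lowest of 5597 by score in replicate 2 (0.137) and the lowest of 5440 in replicate 1 (0.0429). Both clusters are therefore called enriched in one list and depleted, with a score near 0, in the other. How significance and its direction were decided in each list is not given in the sources used here, and no explanation was tested.

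The tests on X scores in this part were chosen after the results were seen; those on the X covered share and on the combined clusters were set beforehand. X clusters had higher score ranks in the middle of the distribution and fewer places at the top. Width would lower X ranks rather than raise them, since X clusters had 0.764 and 0.838 of the autosomal mean width and score rose with width (rho across clusters of 0.80 and 0.81). Within width classes the X lead was 17.5 points in replicate 1, 13.9 in replicate 2 and 9.60 in the combined list. X was higher in 20, 19 and 16 of 20 classes. The fewer places at the top were not matched for width, so narrower X clusters stay open as their source. Weak clusters beside the autosomal centromeres are argued against by the values without the proximal 2 Mb of each arm. The difference was then at least 11.6 points in the replicates and 8.23 in the combined list. A higher score needed for a call on the X stays open for the lead among low and middle scores, where the X minus autosomal difference in score was 0.150 ± 0.00855 at the 10th percentile, but it would not lower the 90th, where the difference was -0.0508 ± 0.0262 (SD, n = 2). Read depth and input on the X also stay open, since neither was analysed here, and no biological explanation was tested. Covered share gave no firm X difference to explain: the permutation test over windows gave p = 0.346 and 0.925. The ratio to the autosomal arms was 0.931 and 0.988 in replicates 1 and 2, and 1.04 in the combined list. With the upper 50% of clusters the replicate ratios became 1.03 and 1.08. Without the proximal parts they were 0.944 and 0.9997, so the ratio of replicate 1 hardly moved.

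The 1125 combined clusters absent from both replicates may have more than one source. Of these, 545 (48.4%, Wilson interval 45.5 to 51.4%) were narrower than 1301 bp, the narrowest width in the replicate lists. The share fell under the bound of 50% set beforehand for a lower width minimum as the main source. Its interval, which was not part of that bound, spans 50%, so whether this was the main source stays open. Narrow width did go with absence: 545 of all 585 combined clusters below 1301 bp lay in neither list, against 580 of the 5471 wider ones. Those 580 were at least 1301 bp wide in the combined list, but the width they would have had in a replicate is unknown. Low score goes with the pattern, as the median score percentile of the 1125 within the combined list was 19.6. It was nearly as low for combined clusters found in replicate 1 only (23.6) or replicate 2 only (21.6), against 65.7 for those in both. Score also rose with width in the combined list (rho across clusters of 0.79), so low score and narrow width were not separated. The 4 highest-scoring combined clusters were exceptions to the low scores, each about 1 kb wide. Of the 8 clusters in the combined top 100 that neither replicate held, 7 were under 1301 bp, and 3 of those 7 lay on heterochromatic or unplaced scaffolds.

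All starts and ends in the combined list were even numbers (100% of both), against 50.6% of starts in replicate 1 and 50.1% in replicate 2. In percentage points of covered share, replicates differed most on X and on chromosome 4, where the share was 26.3% and 28.5%, and 11.0% and 14.1%, in replicates 1 and 2.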
